A study of Homo sapiens with 6 samples.

How the data were processed

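RNA was measured on 6 Affymetrix expression arrays, 3 labelled control and 3 labelled Gli3T, from sorted GFP-positive Panc-1 cells 24 h after transfection. Groups and replicate numbers came from the sample titles. Whether the 3 samples of a group were separate cultures is not stated, so p-values measure only the spread between these samples, which may be technical.

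The authors deposited a table of log2 expression values for 32321 probe sets on the 6 arrays. Tools named in the submitters' processing notes are RMA, oligo and limma, without versions. The array design, annotation release and genome build are not given in the sources used here. Column medians of the deposited log2 values lay between 8.383 and 8.529, and no further normalization was applied to them for the main results. The values are log2 expression with no direction to settle, since each column holds 1 sample. Array data carry no read depth, and the number of arrays limits the precision.

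A second file, the authors' deposited table of changed genes, pairs 405 probe sets with 1 gene symbol each, and 398 of them are in the value table. No other annotation of the probe sets was used, so a probe set outside that table is unnamed here. Set against the value table, its columns proved to be misplaced. In 139 rows the cell under the first sample header holds a number below 0.05, and the samples start 1 column later. In the 135 of these rows found in the value table, the median absolute difference from the value table over the first 5 arrays was 0.00535 when read 1 column later. Over arrays 2 to 5 it was 0.236 when read by the headers. All 135 probe sets were lower in the arrays labelled Gli3T. In the other 263 rows the first 5 arrays agreed to a median of 0.00406, and the sixth value matched its own array within 0.02 in 5 rows. Of the 263 probe sets, 262 rose and 1 fell. The pairing of probe set and values held within that tolerance, as a median over 5 arrays, in 394 of the 398 rows. Whether each symbol belongs to its probe set was not checked, for lack of another annotation. Read by its headers, the table would give 385 rises, against 262 in the value table. For these reasons only the symbols and the adjusted p of the moved rows were taken from it. A column without a name, filled in 140 rows, was not used.

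Of the 405 symbols, 363 are current in the RefSeq gene table for GRCh38.p14, 40 matched as older symbols and 2 did not match. Current symbols are printed, with the older one where they differ. Because the build behind the array annotation is not known, that table was used only for names and for which gene contains a snoRNA, and no coordinates are given.

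Differences are the mean of the arrays labelled Gli3T minus the mean of the arrays labelled control, on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all 32321 probe sets and a threshold of 0.05. Intervals are 95% intervals from the same fit. Probe sets that serve as array controls are not marked in the files, so none was left out. The fit was tested on simulated data with the means and pooled spreads of the real probe sets. The noise was drawn independently for each probe set and array, with the same SD under both labels. In the real arrays the median SD was 0.176 under the control label and 0.0767 under the Gli3T label. The simulated rates that follow may therefore not hold for the real arrays. Of 100 probe sets changed by 1 log2 unit, 72% were called, and of 100 changed by 2 units, 93%. Of the 173 simulated calls, 8 were unchanged probe sets.

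These choices were made before the data were examined: the test, the 30 gene lists, the rule for named genes and the alternatives, except those described as added. The rule takes the 12 largest increases and 12 largest decreases among probe sets with a symbol that passed the threshold without overlap between the groups. It adds GLI3, GLI1, GLI2, PTCH1 and IKBKE, and up to 4 members with the smallest p-values for each list described. Of the 12 largest decreases, 1 is not reported here. GLI1 and GLI2 have no symbol in the authors' table and were not analysed here. A competitive set test (camera) over all genes had been planned. It was not run, because the probe sets that can be named are those the authors chose for changing. The rotation test (fry) and averaging over a gene's probe sets were left out for the same reason. In their place, members that rose and fell were counted. For lists with at least 3 named members, the direction was set against the other called, named probe sets with Fisher's exact test, added after the data were seen.

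The labels do not say that equal replicate numbers share a culture or day, and the numbers were not taken to pair the samples. Alternatives comprised a filter on dim probe sets, a restriction to named probe sets, renewed quantile normalization, median centring, another variance model, array weights, the replicate block, other thresholds and leaving out each array in turn. Leaving out the first unbroken run of 4090 probe-set numbers was added after the data were seen. None of those has a symbol, and their median pooled SD was 0.256, against 0.138 for the others.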

Results

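The effect of Gli3T, a dominant-negative repressor form of the GLI transcription factors, was examined in Panc-1 cells, an established human pancreatic cancer line. Cells received an empty pCIG vector or Gli3T with an IRES-GFP cassette. GFP-positive cells were sorted 24 h later. Total RNA from 3 samples of each kind was hybridised to Affymetrix arrays, giving log2 expression values for 32321 probe sets per array. Array medians ranged from 8.383 to 8.529. The arrays labelled Gli3T were close to one another, with pairwise Pearson correlations across probe sets of 0.995 to 0.996. Those labelled control spread more, from 0.981 to 0.991. The median SD per probe set was 0.176 within the control label and 0.0767 within the Gli3T label. No 2 arrays held identical values.

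GLI3, the gene from which the construct derives, was examined first because it bears on the labels. Its probe set (8139212) was lower in the arrays labelled Gli3T. Log2 expression was 9.21 ± 0.0958 (SD, n = 3) in the arrays labelled control and 7.88 ± 0.152 (SD, n = 3) in those labelled Gli3T. The difference was -1.34 (95% interval -1.59 to -1.08), a 2.52-fold fall, with an adjusted p of 0.00884 in limma. Every array labelled Gli3T lay below every array labelled control. The authors' deposited table gives GLI3 an adjusted p of 0.00836. Without replicates 1, 2 and 3 of the Gli3T label the adjusted p in limma was 0.0695, 0.0868 and 0.0983, which missed the threshold of 0.05, with differences of -1.40, -1.36 and -1.25. Which part of GLI3 the probes cover, and whether they read the construct, is not given in the sources used here. GLI3 thus moved against the label of an overexpressed GLI3 form, unless the probe set does not read the construct, and all directions below are those of the labels as deposited.

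**Figure D1:**
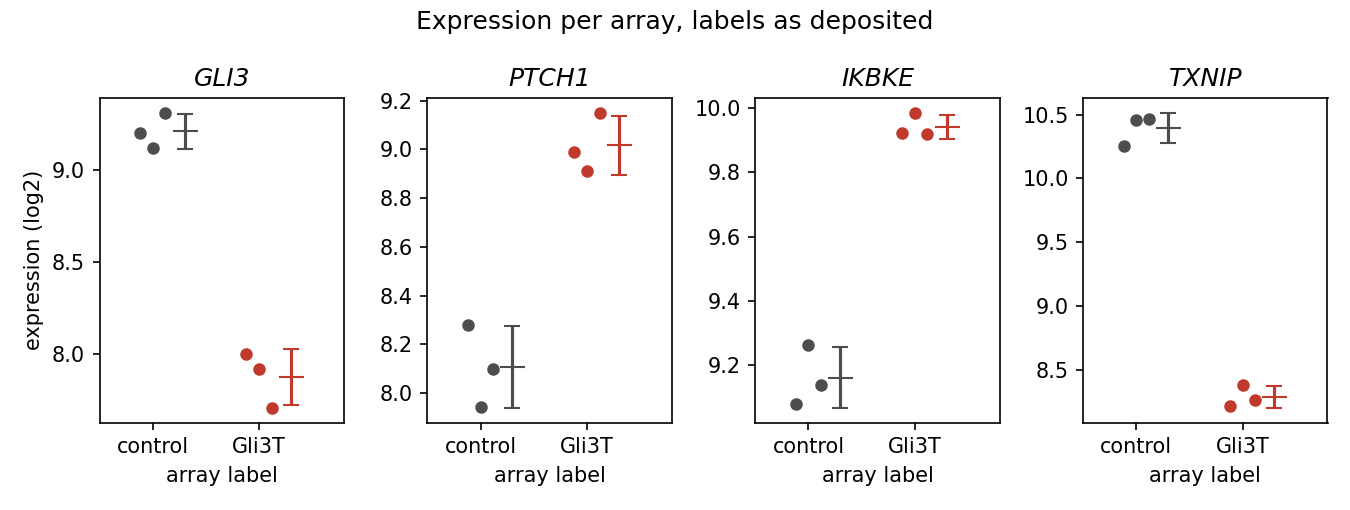
Log2 expression (vertical axis, a separate scale not starting at 0 in each panel) of GLI3, PTCH1, IKBKE and TXNIP in the 3 arrays of each label; points are arrays, and the bars beside them are the mean ± SD. GLI3 and TXNIP were lower and PTCH1 and IKBKE higher in all 3 arrays labelled Gli3T than in any array labelled control.

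PTCH1, which encodes the Hedgehog receptor and is a standard GLI target gene, was higher in the arrays labelled Gli3T. Its probe set (8162533) measured 8.11 ± 0.168 (SD, n = 3) under the control label and 9.02 ± 0.123 (SD, n = 3) under the Gli3T label. The log2 difference was 0.91 (95% interval 0.63 to 1.18), with an adjusted p of 0.0224 in limma. PTCH1 was the 1 member that could be named among the 28 Hedgehog and GLI target genes. The authors had chosen it for changing on these samples, so it is not independent evidence on the list. None of the 28 Hedgehog pathway components could be named. IKBKE, an IKK-related kinase of NF-kB and interferon signalling, was also higher (probe set 7909188). Its log2 difference was 0.78 (SE 0.083, n = 3 per label), with an adjusted p of 0.0166 in limma. Neither PTCH1 nor IKBKE passed without control replicate 3 (adjusted p of 0.0642 and 0.0571 in limma). Without replicates 1, 2 and 3 of the Gli3T label, adjusted p-values were 0.133, 0.108 and 0.137 for PTCH1 and 0.12, 0.108 and 0.127 for IKBKE.

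Across all probe sets, 798 differed between the labels at the adjusted threshold of 0.05 in limma. Of these, 454 were higher and 344 lower in the arrays labelled Gli3T, and in all 798 the groups did not overlap. At changes of at least 2-fold, 150 probe sets were called, of which 31 were higher and 119 lower. Non-overlapping groups were found in 24.4% of all probe sets. The average over all splits into 3 and 3 is 10%. A single split can differ from it because probe sets vary together, and the excess was not tested. An unadjusted p below 0.05 was found for 5285 probe sets, or 16.4%. The count changed when any 1 array was left out, and the balance when any 1 control array was. Without replicates 1, 2 and 3 of the Gli3T label, limma called 0, 1 and 0 probe sets, while 3471, 3751 and 3469 had an unadjusted p below 0.05. Without replicates 1, 2 and 3 of the control label it called 2178, 548 and 69, of which 48.3%, 41.1% and 43.5% were higher, against 56.9% of the 798 (43.8% with array weights).

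**Figure D2:**
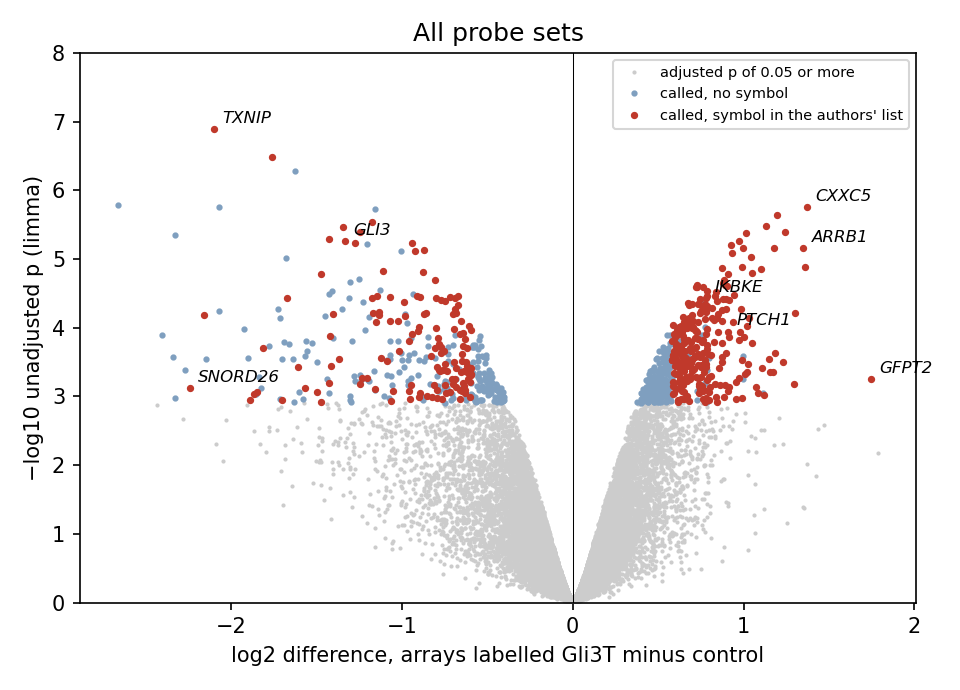
Each point is 1 of the 32321 probe sets, with the log2 difference between labels on the horizontal axis and −log10 of the unadjusted limma p on the vertical axis; red points are called and named, blue points are called without a symbol, grey points are not called. The 150 calls of at least 2-fold lay mostly on the lower side (119), while calls of smaller size lay more often on the higher side.

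The 12 largest increases of named genes in the arrays labelled Gli3T lay between 1.17 and 1.74 on the log2 scale. GFPT2, an enzyme of the hexosamine pathway, rose by 1.74 (SE 0.288). CXXC5, a CXXC zinc finger protein, rose by 1.37 (SE 0.0917), and ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 1.36 (SE 0.123). ARRB1, which encodes beta-arrestin 1, rose by 1.35 (SE 0.111). The transmembrane protease TMPRSS2 rose by 1.30, the chemokine CX3CL1 by 1.30 and DEPP1 (listed as C10orf10) by 1.24. PIK3R1, a regulatory subunit of phosphoinositide 3-kinase, rose by 1.23 and the transcriptional coregulator ZMIZ1 by 1.20. TNFSF10, which encodes the death ligand TRAIL, rose by 1.19, TBC1D8 by 1.18 and the acyltransferase MBOAT1 by 1.17. Adjusted p-values of these 12 in limma ran from 0.00863 for CXXC5 to 0.0393 for CX3CL1. Of the 54 called genes that the rule or a list names, 36 missed the threshold without control replicate 3, and 54, 53 and 54 missed it without replicates 1, 2 and 3 of the Gli3T label.

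Over all probe sets the largest called fall was -2.66, of a probe set without a symbol. Among named genes, small nucleolar RNAs, which guide modification of ribosomal RNA, made up 10 of the 12 largest decreases. The log2 differences were -2.24 (SE 0.390) for SNORD26, -2.16 (SE 0.251) for SNORD25, -1.89 for SNORD27, -1.86 for SNORD31 and -1.85 for SNORD28. These 5 lie within the host gene SNHG1. SNORD14E (-1.81), SNORA75 (-1.70), SNORA1 (-1.67), SNORD4A (-1.61) and SNORD45C (-1.57) fell as well, each within a different host (HSPA8, NCL, TAF1D, RPL23A and RABGGTB). Such probe sets may also read the intron of the host transcript, and the snoRNA values varied more among the control arrays (SNORD26 SD 0.862, against 0.119 under the Gli3T label). TXNIP, an inhibitor of thioredoxin and glucose uptake, was also among the 12. TXNIP fell by 2.10 (SE 0.0953), from 10.4 ± 0.119 to 8.29 ± 0.0850 (SD, n = 3 per label). Adjusted p-values in limma were 0.00419 for TXNIP and 0.0414 for SNORD26. With array weights 5 of the snoRNA differences shrank by over 1.5 times, to -1.16 for SNORD27, -1.21 for SNORD31 and for SNORD28, -1.11 for SNORA75 and -0.97 for SNORD45C. After quantile normalization SNORD27, SNORD31, SNORD28 and SNORA75 missed the threshold in limma (adjusted p of 0.0565, 0.0565, 0.0514 and 0.0605). After median centring SNORD27 missed it too (0.0509), as did CX3CL1, FOS, CDK1, H1-5 and RRM2B (0.0504 to 0.0656). Of 36 snoRNAs in the authors' table limma called 35, and 26 after quantile normalization. It called 36, 33 and 0 without control replicates 1, 2 and 3, and 0 without any 1 array labelled Gli3T. All 36 kept an unadjusted p below 0.05 in each fit without 1 array.

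NF-kB genes were examined as a group fixed beforehand, and 6 of the 34 NF-kB target genes could be named. Of these 6, 5 rose in the arrays labelled Gli3T and 1 fell. TNFAIP2 rose by 1.04 (SE 0.0897), CFLAR, an inhibitor of caspase-8 activation, by 0.88, and the adaptor TRAF1 by 0.77. NFKBIE, an inhibitor of NF-kB, rose by 0.68 and the anti-apoptotic BCL2L1 by 0.59. CXCL8 (listed as IL8), a neutrophil chemokine, fell by 1.47 (SE 0.138), with an adjusted p of 0.0132 in limma. Among 19 NF-kB subunits and IKK kinases, IKBKE and NFKBIE could be named, and both rose. The named members of each list had been chosen by the authors for changing on these samples, so their counts are not independent evidence of direction. For the same reason, that the named members of each list passed when adjusted over the list alone was fixed beforehand and adds nothing to the values over all probe sets. The split of the 6 targets was not distinguished from that of the other called, named genes (252 rose, 133 fell; Fisher's exact test, two-sided, p = 0.669). Limma called 1 of the 5 rises without control replicate 3 and 0 without any 1 array labelled Gli3T, where all 5 had an unadjusted p below 0.05.

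Most named members of the immediate early and stress lists were lower in the arrays labelled Gli3T. Among 20 immediate early genes, 4 could be named, 3 fell and 1 did not pass. ATF3, a stress-induced transcription factor, fell by 1.42 (SE 0.112). The log2 differences of EGR1 and FOS were -0.88 (SE 0.0816) and -0.77 (SE 0.107). FOSB differed by -0.67, with an adjusted p of 0.0514 in limma. Of 27 genes of the unfolded protein and ATF4 response, 5 could be named, 4 fell and 1 rose. SLC7A11, the cystine transporter, fell by 1.28, and DDIT3, which encodes CHOP, fell by 0.94. SESN2 fell by 0.86, while DDIT4, an inhibitor of mTORC1, rose by 1.03. Fisher's exact test of direction against the other called, named genes gave p = 0.0397 for the immediate early list and p = 0.049 for the unfolded protein and ATF4 list, 0.122 for both after adjustment over the 5 lists tested. Neither passed after adjustment, and the members were again chosen by the authors on these samples. Of the 3 and 4 falls, 2 and 3 were called without control replicate 3, 2 and 4 without control replicate 2, and 0 without any 1 array labelled Gli3T, where all had an unadjusted p below 0.05 in limma.

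**Figure D3:**
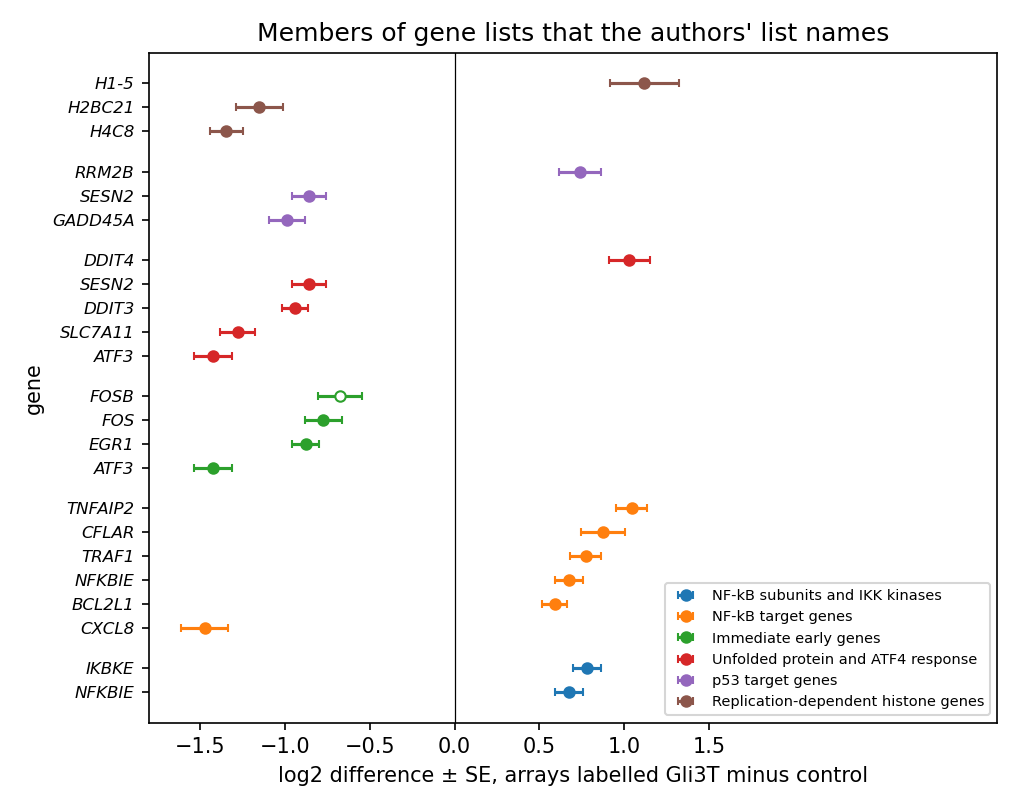
Log2 difference between labels (horizontal axis, points ± SE, n = 3 per label) for the named members of 6 gene lists; filled points are called at an adjusted p below 0.05 and the open point, FOSB, is not. ATF3, SESN2 and NFKBIE appear under 2 lists each.

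Members of the other lists were few. Of 23 p53 target genes 3 could be named. GADD45A fell by 0.99, SESN2 fell by 0.86, and RRM2B, a p53-induced ribonucleotide reductase subunit, rose by 0.74. Of 23 replication-dependent histone genes, H4C8 (listed as HIST1H4H) fell by 1.34 and H2BC21 (HIST2H2BE) fell by 1.15, while H1-5 (HIST1H1B) rose by 1.12. The histone genes H3C11 (HIST1H3I) and H2BC14 (HIST1H2BM), outside the fixed list and named after their values were seen, rose by 0.86 and 0.75, so the named histone genes had no common direction. Histone genes are near-identical copies, so their probe sets can share signal. For the p53 list and the fixed histone list, Fisher's exact test gave p = 0.271 each. The G2/M genes CDK1 and UBE2C rose by 0.85 and 0.74. The apoptosis regulators named were BCL2L1 and CFLAR, given above. FOXA2, a foregut and pancreatic transcription factor, rose by 1.10, CDH3 (P-cadherin) by 0.68, LIF by 0.62 and the NOTCH target HES1 by 0.58. VEGFA rose by 0.69, and SLC2A1, the GLUT1 glucose transporter, differed by 0.76 with an adjusted p of 0.0501 in limma. The chaperone gene DNAJB4 fell by 1.18 and TGFB2 fell by 0.61. SLC7A11 was also the 1 named NRF2 target, and TGFB2 and GADD45A the 2 named YAP/TEAD targets.

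No member could be named in 12 of the 30 lists. These were Hedgehog pathway components, interferon-stimulated genes, G1/S and replication genes, cholesterol synthesis genes, BMP and ID genes and WNT target genes. Metallothioneins, ribosomal protein genes, oxidative phosphorylation genes and the markers of acinar and islet cells, of fibroblasts and endothelium, and of leukocytes completed the set. The genes of these lists are not in the authors' table, and their expression in the value table was not analysed here because the probe sets carry no symbol. The lists do not hold every gene of their class. Outside them, and named after their values were seen, the ribosomal protein gene RPL27A fell by 0.80 and the respiratory complex III gene UQCRB fell by 0.87, while the interferon-induced genes IRF1 and PARP14 rose by 0.97 and 0.60.

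The authors' deposited table of changed genes was set against the limma fit. Of its 398 probe sets in the value table, 391 (98.2%) were called here, 257 of them higher and 134 lower. The other 7 had adjusted p-values of up to 0.0603. The smallest change among the 398 was 1.49-fold. In the whole value table, 534 probe sets were called with at least a 1.5-fold change, 270 higher and 264 lower. Of these 534, 149 have no symbol in the authors' table, and 130 of the 149 were lower. The first run of probe-set numbers, with its larger spread, held 102 of the 149 and 92 of the 130.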

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

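Leaving out the first run of probe-set numbers, the direction tests of the gene lists and the counts per gene group were chosen after the data were seen. The sign of the difference was the same under every alternative run for GLI3, PTCH1, the NF-kB target median and all other genes named by the rule or through a list. The size moved by over 1.5 times for 5 of those genes, all snoRNAs with array weights. Calls numbered 798 in the main analysis. There were 1446 among probe sets above the median mean, 1199 with a trended and robust variance model, 7104 with array weights, 5285 at an unadjusted p below 0.05 and 1804 at an adjusted p below 0.1. With named probe sets only, all 398 were called, as fixed by the authors' choice of them. At 2-fold the 150 calls became 75 with named probe sets only, 105 without the first run of probe-set numbers and 259 with array weights. Percentages of calls that were higher, 56.9 in the main analysis, were 66.5 above the median mean, 65.8 with named probe sets, 61.3 after quantile normalization, 64.2 after median centring, 43.8 with array weights and 64.2 without the first run of probe-set numbers. Array weights gave control replicates 1, 2 and 3 weights of 0.133, 4.46 and 0.372, so control replicate 2 dominated the weighted control mean. The deviations of same-numbered samples from their group means correlated at -0.304, -0.142 and 0.0441, so the numbers were not taken to pair them. No control sample correlated best with the Gli3T sample of its own number. With the replicate block, 240 probe sets were called, 181 of them among the 798, 21.3% of them higher, and 26.6% of the authors' listed probe sets passed. GLI3 (adjusted p = 0.023 in limma) and PTCH1 (0.0435) kept their calls under the block, while 16 other genes named by the rule or through a list missed the threshold, NF-kB targets called higher went from 5 to 1 and ZNF genes called lower from 12 to 2. Leaving out 1 array at a time gave 0 to 2178 calls, 0 to 224 at 2-fold, 0% to 48.3% higher (41.1% to 48.3% without a control array, the 0% being 1 call, with no share where 0 were called) and 0% to 99.5% of the authors' probe sets called (11.3% without control replicate 3). Without control replicates 1, 2 and 3 the calls numbered 2178, 548 and 69 (43 at 2-fold). The lowest counts came without any 1 array labelled Gli3T (0, 1 and 0). In those 3 fits GLI3 (-1.40 to -1.25, adjusted p 0.0695 to 0.0983) and PTCH1 missed the threshold, as PTCH1 did without control replicate 3 (0.0642). Over the 6 fits without 1 array PTCH1 ranged from 0.83 to 0.99. Over all 14 alternatives the adjusted p ran from 2.3e-05 to 0.0983 for GLI3 and 8.65e-05 to 0.137 for PTCH1. Both low ends, with named probe sets only, were fixed by the authors' choice. Quantile normalization ended 4 calls of named genes and median centring 6. Of the 36 listed snoRNAs, 17 lay above the median mean, and all 17 were called there. Apart from the filters, the cause of these changes was not tested. Signal over background is not given in the sources used here. Camera, fry and the mean over a gene's probe sets were not run, for lack of symbols.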

Other observations

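The tests of a label exchange and of independent noise were chosen after the results were seen, as were the gene groups and single genes of the next 2 paragraphs.

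Beyond the fixed lists, the authors' table held 36 snoRNAs, and all 36 were lower in the arrays labelled Gli3T, with a median log2 difference of -1.22 (range -2.24 to -0.64). Limma called 35 of them. SNHG1 contains 6, GAS5 contains 4, and RPL23A contains 3. The host genes RABGGTB (of SNORD45C), TAF1D (of SNORA1 and SNORD5) and ZFAS1 (listed as C20orf199, of SNORD12C) are themselves listed. RABGGTB fell by 0.90, TAF1D fell by 0.66 and ZFAS1 fell by 0.60. No other host, SNHG1, GAS5 and RPL23A included, is among the named probe sets, so their change was not analysed here. Of 13 genes listed under a ZNF symbol (1 of them, ZNF673, now named KRABD4), 12 fell and 1 rose. Among the other listed genes 261 were higher and 88 lower. Both groups were formed after their direction was seen, from genes that the authors had chosen on these samples, so the counts are not independent evidence. Those 36 and 12 were lower after quantile normalization and median centring too, but fewer were called. Limma called 26 of the 36 snoRNAs after quantile normalization, 33 after median centring and 26 with the replicate block. It called 12 ZNF genes lower, 10 after quantile normalization, 3 after median centring, 3 without control replicate 2 and 0 without control replicate 3 or any 1 array labelled Gli3T, where all 12 had an unadjusted p below 0.05.

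Single genes outside the lists were picked for their known roles after their values were seen. They form no group, since 257 of the 391 called, named genes rose in the arrays labelled Gli3T. STING1 (listed as TMEM173) rose by 0.80 and CGAS (listed as C6orf150) by 0.66, the adaptor and the sensor of cytosolic DNA. IRF1 rose by 0.97, TNFRSF1B by 0.99, BCL3 by 0.87, TRAF3IP2 by 0.86, PYCARD by 0.79 and RIPK1 by 0.62. The growth factors PDGFA and PDGFB rose by 0.76 and 0.72. ARRDC4, an arrestin family member related to TXNIP, fell by 0.80. No enrichment was tested. Of all the authors' listed probe sets, 11.3% passed in limma without control replicate 3, and 0%, 0.251% and 0% without replicates 1, 2 and 3 of the Gli3T label.

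GLI3 was lower and PTCH1 higher in the arrays labelled Gli3T, the opposite of what added GLI3 sequence and repression of a GLI target would give. Of the arrays labelled Gli3T, 0 reached the GLI3 level of any array labelled control. That cannot decide on an exchange of 1 array of each group. GLI3 could be named only because the authors chose it for changing between these labels, and no called probe set overlapped. An exchange of both whole sets of labels may account for both genes, with GLI3 at -1.335 and no overlap in either gene, but it was proposed from these values, which therefore cannot bear it out. It stays open, because the part of GLI3 that the probe set reads, the species of the construct and indirect effects on PTCH1 are untested, and GLI1 and GLI2 were not analysed here.

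The fall of the listed snoRNAs was weighed next. Without control replicates 1, 2 and 3, limma called 36, 33 and 0 of the 36. All 36 were lower with an unadjusted p below 0.05 in each of those fits. The fall was thus seen without any 1 control array. These fits cannot settle whether a single deviating control array added to it, since the 36 had been chosen for a fall over these arrays. Independent noise of short probe sets is argued against by their values within the control label, where the median pairwise Pearson correlation of the 36 over the 3 arrays was 0.886. Shuffling each snoRNA's control values 1000 times gave at most 0.219. A shared factor of single samples, such as small RNA recovery, could still have moved all 36 together, and it cannot be told apart from the construct. The gap between the groups was 1.3 times the largest range within a group, 3 arrays against 3 allow no exact p below 0.1, and the snoRNA medians ranged over 0.649 among the control arrays.

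Among all 10 splits of the 6 arrays into 3 and 3, each counted once, 1 (the real split) called as many as 798 probe sets in limma, and the highest of the others called 0. At 2-fold and at 1.5-fold the real split gave 150 and 534, was again the 1 split to reach them, and the highest other gave 0. With 10 splits no share below 0.05 can be reached. At an unadjusted p below 0.05, the other splits gave up to 2094 probe sets, against 5285.

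Of the 798 calls, 407 were of probe sets without a symbol, and what they measure was not analysed here. The first run of 4090 probe-set numbers held 120 calls, and 92 of its 102 calls of at least 1.5-fold were lower. Its median log2 difference was -0.16, against -0.04 for the other probe sets.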
